A study of Escherichia coli with 5 samples.

How the data were processed

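The series holds 5 RNA-seq libraries of Escherichia coli DY330, 1 for each of 0, 2, 4, 6 and 8 min after rifampicin. Per the labels' protocols, RNA was extracted with phenol and chloroform, ribosomal RNA was removed in a pair of steps, the remaining RNA was fragmented, and libraries with barcoded adapters were pooled and run on an Illumina GA II. For each library the authors deposited a table of raw read counts per gene without a header, and the last entry of each table names no gene. The aligner, the counting rule, its strand, the genome build and the annotation are not given in the sources used here. The file names carry a pair of letters (CC at 0 and 4 min, GG at 2 and 6 min, CG at 8 min) and a number (7 at 0 and 2 min, 8 at 4, 6 and 8 min) which resemble adapter barcodes and lanes, but no label says so. A table of the whole series, deposited by the authors, gives 1 lifetime value per gene without a unit and with a ceiling of 150; how it was made is not given in the sources used here.

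Each count table had 4414 entries. For 13 repeated names the repeats were identical and 63 were dropped, which left 4350 genes. Symbols were matched to a gene table of assembly ASM584v2 (MG1655), used for names and neighbours only: 3669 were current symbols, 665 older synonyms and 16 had no match. Since the build of the files is not named, no coordinates are printed. Counts that fell in no gene (7.67% of reads at 0 min, 7.08%, 6.13%, 5.90% and 5.02% at the later times) stayed out of library sizes and tests. 284 genes had 0 counts in all libraries.

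The change with time was fitted in R 4.3.3 with edgeR 4.0.16, by quasi-likelihood (glmQLFit, glmQLFTest) with time as a number, so that the coefficient is the fitted log2 change over 8 min. Libraries were scaled by TMM, and genes with a mean of at least 10 counts over the 5 libraries were tested (2239 genes holding 98.78% of gene reads). The fit had 3 residual degrees of freedom, a common dispersion of 0.0243 and 20.8 prior degrees of freedom, and p-values were adjusted by Benjamini and Hochberg, with 0.05 as the threshold. In words, rose and fell mean passing that threshold. SE and standard error mean the size of the fitted change divided by the square root of its F statistic. They were not estimated separately for the coefficient. TMM factors ran from 1.45 at 0 min to 0.56 at 8 min. Ratios of single libraries to 0 min carry conditional exact binomial 95% intervals. Gene lists were compared with limma 3.58.1's camera, with a preset correlation of 0.01 and with an estimated one. Operon position and correlations were tested with 100000 permutations, and lists of lifetime values were set against 10000 random lists.

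The method was tested on simulated data in which the real means and library sizes were kept and known slopes were added. Of 92 genes changed by a log2 value of 1 over 8 min, 18.5% were recovered, and of 94 changed by 2, 84.0%. A missed call at a small change therefore says little. Of 98 calls 2.04% were false. The simulated genes were independent, shared a common dispersion, changed along straight lines and carried no effect of single libraries. That share is therefore no estimate of false calls in the real libraries, where such effects cannot be separated from time.

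The tests, 31 gene lists, the operons and the rule for named genes were fixed before the data were examined. Genes are named if they are among the 10 steepest falls or rises past the threshold, among the 10 longest or shortest lifetimes of tested genes, among 20 fixed textbook transcripts, or among the 2 highest and 2 lowest members of a list that is described. Other genes along the operons, and genes of the lists of regulators, tRNAs and leader peptides in the closing part, were named after their values were seen. Alternatives were size factors and a Wald test from DESeq2 1.42.0, total counts, scaling to the summed ssrA, rnpB, ssrS and ffs counts, no filter, a mean of at least 50 counts, limma-voom, the number in the file names beside time, and leaving out each library. Where a scaling moved the median of all genes by more than 0.1, single genes and lists were compared relative to that shift. Figures were drawn with matplotlib 3.10.9.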

Results

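RNA abundance was followed in Escherichia coli strain DY330, a W3110 derivative, after transcription was blocked. Cells grew at 30 °C in a defined M9 medium with 0.4% glucose plus amino acids and vitamins. Rifampicin, an antibiotic that binds bacterial RNA polymerase and stops new transcripts from being started, was given at 500 µg/ml, and RNA was taken at 0, 2, 4, 6 and 8 min. Each time point was 1 RNA-seq library, so no pair of times could be compared against replicate error, and calls for genes and lists rest on a trend over the 5 libraries with 3 residual degrees of freedom. Tests along operons and correlations permute genes, some of them on ratios of single libraries. The labels do not say whether the time points came from separate cultures, so p-values of the trend measure only the scatter of these 5 libraries around a straight line. Each gene's scatter was also drawn towards that of all tested genes, with 20.8 prior degrees of freedom beside the 3 residual ones. Small p-values therefore rest largely on scatter pooled over genes. The libraries held 737107 reads in genes at 0 min, 862243 at 2 min, 265650 at 4 min, 304538 at 6 min and 292827 at 8 min. A count of 0 allowed a level of up to 4.07 CPM at 0 min and 10.2 at 8 min (3 counts), and these floors, like all intervals given here, cover counting error only. The libraries at 0 and 2 min were deeper than the later 3, and 448 of 4350 genes had no read at 0 min against 1440 at 8 min.

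The first question was which transcripts lasted and which were lost once no new RNA was started. The RNA pool shifted towards the 4 stable housekeeping RNAs: tmRNA (ssrA), which rescues stalled ribosomes, the catalytic RNA of RNase P (rnpB), 6S RNA (ssrS) and the signal recognition particle RNA (ffs) together took 15% of gene reads at 0 min and 34.1% at 8 min. ssrA alone went from 11% (95% exact binomial interval 10.9% to 11.1%) to 25.6% (25.4% to 25.8%). Counted against these 4 RNAs, the median gene had a fitted log2 change of −2.74 over 8 min (quartiles −3.93 and −1.62, 2239 genes). By the straight-line slope, the 2191 genes with a change below 0 had a median halving time of 2.89 min (quartiles 2.02 and 4.73 min). On that scale 1924 genes fell and 1 rose in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05). The gene that rose was yfbP, at a log2 change of 1.85 (SE 0.56, edgeR adjusted p = 0.00444). The halving times assume a straight line and leave out genes that did not fall. Median log2 ratios of single libraries to 0 min were −0.47, −0.79, −1.85 and −2.80 at 2, 4, 6 and 8 min, a larger drop after 4 min than before. Among tested genes 125 had 0 counts at 8 min. The halving times therefore need not be decay times.

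Each library is also a fixed pool of reads, and on the TMM scale, which sets every gene against the average transcript of its library, the genes split: 515 rose and 616 fell out of 2239, with a median log2 change of −0.32 (quartiles −1.58 and 0.86). A gene that rose on this scale kept its level better than the average transcript and need not have gained molecules. Slower decay and RNA finished by polymerases that had already started cannot be told apart by the trend. With libraries scaled to their total counts, 84 genes rose and 1306 fell, and the median moved by −1.29 from its TMM value. With the stable RNAs it moved by −2.42. All changes from here on are relative to the TMM average. Fitted changes and calls of single genes given below with total counts or the stable RNAs are relative to the median shift of that scale. A call lost there does not mean that the gene kept its level against those RNAs. With the number carried by the file names (7 at 0 and 2 min, 8 at 4, 6 and 8 min) beside time, 250 genes passed, 187 higher and 63 lower. That number overlaps with time (r = 0.866 over the 5 libraries), and with it the median standard error went from 0.5 to 1.13, so calls were lost also where the change was as large or larger. Leaving out 1 library at a time gave between 913 and 1161 genes. The share of reads that fell in no gene went down over the same times, from 7.67% at 0 min to 5.02% at 8 min.

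Set library against library on the TMM scale, genes parted in both directions from 2 min on. The 95% counting interval of the ratio to 0 min lay above 1 for 347 and below 1 for 305 of 2239 genes at 2 min, for 518 and 432 at 4 min, 588 and 631 at 6 min and 607 and 612 at 8 min. Against the stable RNAs these counts were 15 above and 1260 below at 2 min, 55 and 1304 at 4 min, 16 and 1947 at 6 min and 12 and 2095 at 8 min. With total counts they were 192 and 452 at 2 min, 251 and 803 at 4 min, 233 and 1287 at 6 min and 179 and 1573 at 8 min. On the TMM scale, which holds it near the average, the median ratio was 0.01 on the log2 scale at 2 min, −0.02 at 4 min, −0.14 at 6 min and −0.26 at 8 min. Against the stable RNAs the same medians were −0.47, −0.79, −1.85 and −2.80, and with total counts they were −0.11, −0.39, −0.96 and −1.62. lpp, which encodes the abundant Braun lipoprotein of the outer membrane, was at 1.05 times its 0 min level at 2 min (95% counting interval 1.03 to 1.07) and at 4.49 times at 8 min (4.37 to 4.61). ompA was at 2.79 times (2.67 to 2.92) at 8 min. These TMM ratios turn below 1 against the stable RNAs, where lpp was at 0.755 times its 0 min level at 2 min (0.738 to 0.773) and 0.768 times at 8 min (0.748 to 0.789), and ompA at 0.478 times at 8 min (0.457 to 0.5001). spr, a gene for a murein endopeptidase, had 587 counts at 0 min, 295 at 2 min, 18 at 4 min and 2 at 8 min, a TMM ratio of 0.022 at 8 min (0.0027 to 0.080) and 0.0038 (0.00046 to 0.014) against the stable RNAs. These ratios compare single libraries and carry no replicate check. Most reads of the stable RNA scale were ssrA, with 15.4% of gene reads at 2 min out of 19.3% for all 4. On the TMM scale ssrA was at 1.51 times its 0 min level at 2 min and rnpB at 1.11 times. At 6 min they were at 3.54 and 2.69 times, and at 8 min at 5.98 and 5.64 times. Values against the stable RNAs at 2 and 6 min therefore depend on which RNA sets the scale.

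**Figure D1:**
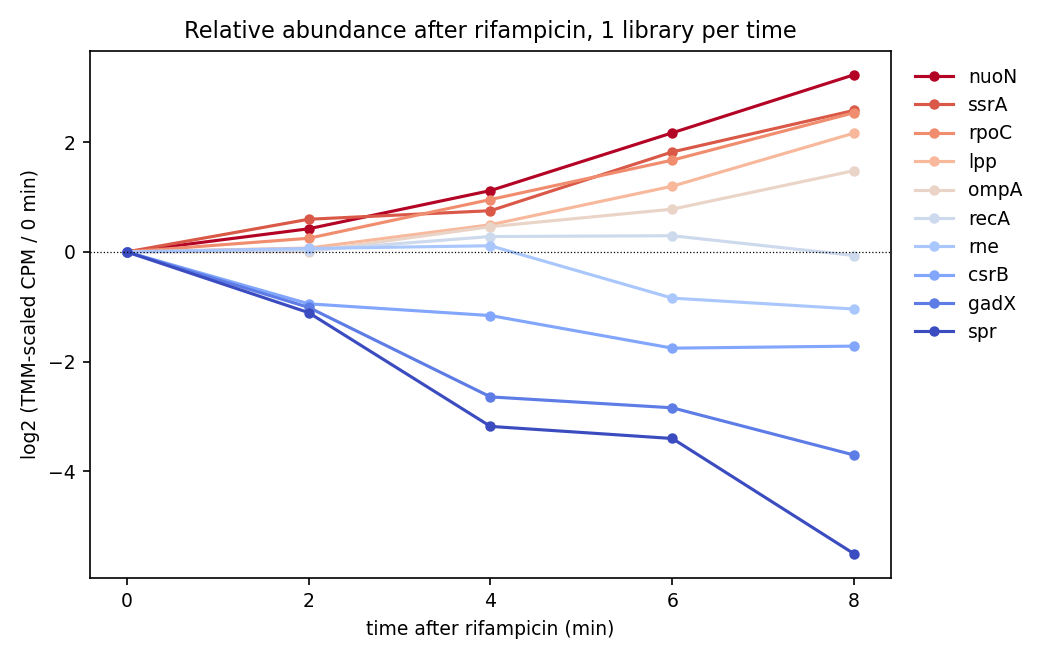
Abundance relative to 0 min (log2 of TMM-scaled CPM over its 0 min value) against time after rifampicin in minutes, 1 point per library and 1 line per gene for 10 genes. The lines fan out from 0 min, with nuoN, ssrA, rpoC, lpp and ompA above 0 at 8 min, recA near 0, and rne, csrB, gadX and spr below it.

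The 10 steepest falls were those of hisL, cysT, leuZ, leuT, ivbL, metN, yliL, hisR, ydcK and nanR. hisL, the leader peptide gene of the histidine operon, had 55 counts at 0 min, 9 at 2 min, 1 at 4 min and 0 after that, with a fitted log2 change of −9.76 (SE 1.35). ivbL, the leader peptide gene ahead of ilvB, had 125 counts at 0 min and 2 at 8 min (−6.94). The tRNA genes cysT (−7.79), leuZ (−7.13), leuT (−7.00) and hisR (−5.81) fell as well, with leuT uncertain because near-identical copies of it exist. The other 4 of the 10 were metN (−6.48), the ATP-binding subunit of a methionine transporter, nanR (−5.76), the repressor of sialic acid use, and the little-known yliL (−5.92) and ydcK (−5.77). Fitted values of genes that reach 0 are no bounds, and their SEs do not cover this. Against a floor of 3 counts at 8 min, hisL was at least 2.83-fold lower than at 0 min, leuZ 5.62-fold and leuT 4.53-fold. By the same floor metN was at least 2.58-fold lower, hisR 5.10-fold, yliL and nanR 3.25-fold and ydcK 2.01-fold. All 10 passed (edgeR adjusted p between 3.99e-06 and 0.000199), but without the 0 min library hisL (−6.49, adjusted p = 0.104), cysT (−3.01, 0.166), leuZ (−3.08, 0.153), leuT (−3.26, 0.186) and ivbL (−1.28, 0.524) did not, and the values of yliL (−9.38) and ydcK (−9.79) were larger. nanR ran from −20.84 (without 0 min) to −4.74 (without 4 min), and leuT was at −11.01 without the 4 min library. With the file name number beside time, yliL (−4.66), hisR (−4.95), ydcK (−4.28) and nanR (−1.88) lost the call and leuT was at −11.51. nanR was at −14.49 with the mark of the 2 and 6 min libraries beside time. It lost the call in DESeq2 at a larger change (−7.18, Wald test adjusted p = 0.156). ivbL was at −4.50 in DESeq2, and hisL was at −5.29 in limma-voom.

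The 10 steepest rises were those of yfbP, ugd, gabP, nuoN, rfaZ, nuoM, narV, phnK, phnL and yfgJ. nuoN (log2 change 3.29, SE 0.26, edgeR adjusted p = 6.58e-09) and nuoM (3.22, SE 0.25) encode membrane subunits of NADH dehydrogenase I, and phnK (3.16) and phnL (3.11) belong to the phosphonate degradation cluster. ugd (3.64), the UDP-glucose dehydrogenase gene, gabP (3.30), the permease for 4-aminobutyrate, rfaZ (3.24) of the lipopolysaccharide core and narV (3.20) of the minor nitrate reductase rose too. The largest value was that of yfbP (4.44, SE 0.52), a gene of unknown function listed next to nuoN, with 11 counts at 0 min and 32 at 8 min, and the last of the 10 was yfgJ (3.04). The strand used in counting is not given in the sources used here, so reads of overlapping or antisense neighbours may be part of a gene's count. With the file name number beside time, rfaZ (2.50), narV (2.32) and yfgJ (2.07) did not pass.

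Of 20 fixed textbook transcripts some kept their level better than the average and others less well. lpp had a log2 change of 2.18 (SE 0.27), the porin genes ompC and ompF 1.69 and 1.33, ompA 1.49 (SE 0.25), cspC 1.59, rpoS, the general stress sigma factor, 1.40, hdeA, the acid-stress chaperone, 1.23 and gadB, glutamate decarboxylase, 1.15, the last uncertain because of its near-identical partner gadA. ssrA (2.56) and rnpB (2.51) rose most among the 20. Falls were found for rpoH, the heat shock sigma factor (−1.66), rne, which encodes RNase E (−1.10), cspE (−0.96), rpsT (−0.81) and cspA, the major cold shock gene (−3.19, SE 0.80). pnp (0.36), rpsO (0.38), trxA (0.41) and recA (0.13) did not pass, with edgeR adjusted p of 0.214, 0.184, 0.206 and 0.747, and lacZ had 0 counts in all 5 libraries. Over the left-out libraries pnp ran from 0.08 to 0.41, rpsO from −0.23 (without 8 min) to 0.74 (without 0 min, adjusted p = 0.0422), trxA from 0.00 to 0.99 (highest without 0 min, 0.0249) and recA from 0.00 to 0.35. cspA rested on the 0 min library, where it had 149 counts against 30 at 2 min: without it the value was 0.28 (adjusted p = 0.845), and without the 8 min library it was −5.97. rne lost its call without the 6 min (−0.94, adjusted p = 0.0608) or the 8 min library (−0.93, 0.0692) and was at −1.66 without the 0 min library. rpsT (−0.80, 0.0554) and gadB (0.74, 0.0626) lost theirs without the 8 min library. There cspC was at 0.92 and hdeA at 0.79. With the file name number beside time, cspA (−3.95), cspE (−0.61), rne (−1.72), rpsT (−0.42), rpoH (−1.64) and gadB (1.34) did not pass and recA was at −0.44. cspA did not pass in DESeq2 (−2.08, 0.116). Relative to the median shift of the stable RNA scale, rne (−1.22, 0.0716) and rpsT (−0.91, 0.0763) did not pass with the stable RNAs.

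Gene lists written before the data were examined were then compared with all other tested genes. That comparison was not matched on level at 0 min. Of 31 lists, 14 stood higher and 1 lower (camera of limma with a preset correlation of 0.01, Benjamini-Hochberg adjusted p under 0.05). With an estimated correlation none of the 15 passed, the smallest adjusted p being 0.250, and 4 were under 0.05 before adjustment. Members of a list often share an operon, which is 1 way for them to move together. With libraries scaled to total counts 7 lists passed, and with the stable RNAs 3 (NADH dehydrogenase I, the stable RNAs, and RNA decay and processing). The stable RNA list holds the same 4 RNAs that set this last scale, so its pass there is no separate check. With genes of at least 50 counts on average 5 passed. They were NADH dehydrogenase I, the RpoS genes, RNA decay and processing, and, lower, the aminoacyl-tRNA synthetases and iron uptake. With at least 50 counts the iron uptake median less that of all genes was −3.32 (camera adjusted p = 0.0312, preset correlation). In the main fit it was −0.08 (camera adjusted p = 0.122, and 0.450 with an estimated correlation). With the file name number beside time all 15 passed, and so did the aminoacyl-tRNA synthetases.

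Genes of respiration and central carbon use stood above the average of all tested genes, which were not matched on level. Of the 13 genes of NADH dehydrogenase I, which passes electrons from NADH into the respiratory chain, 9 rose, 0 fell and 4 did not pass (10 rose adjusted over the list alone; median log2 change 2.44; camera adjusted p = 5.56e-09, adjusted p = 0.250 with an estimated correlation), from nuoB (−0.33, adjusted p = 0.415) and nuoA (0.15, 0.732) to nuoM and nuoN. Of the 9 ATP synthase genes 7 rose and 2 fell, with the same counts adjusted over the list alone (median 1.10; camera adjusted p = 0.00408, adjusted p = 0.250 with an estimated correlation), with atpI (−2.93) and atpB (−0.73) at the low end and atpD (2.26) and atpC (2.59) at the high end. The terminal oxidases, the enzymes that hand electrons to oxygen, had 5 of 7 members higher and 0 lower (6 and 1 adjusted over the list alone; median 1.30; camera adjusted p = 0.00947, adjusted p = 0.250 with an estimated correlation), from cyoA (−0.56, adjusted p = 0.0676) to cyoE (1.94). In the TCA cycle 9 of 16 rose and 1 fell (9 and 2 adjusted over the list alone; median 1.12; camera adjusted p = 0.00149, adjusted p = 0.250 with an estimated correlation), from sdhC (−1.53) and sdhD (−1.07, adjusted p = 0.0565) to sucB (2.44) and sucD (2.52). In glycolysis 9 of 13 rose and 1 fell, also adjusted over the list alone (median 1.10; camera adjusted p = 0.00408, adjusted p = 0.250 with an estimated correlation), with pgi (−0.99) lowest and pfkB (1.68) and fbaB (1.86) highest. Of 12 genes of the sugar phosphotransferase system 8 rose and 0 fell, also adjusted over the list alone (median 1.13; camera adjusted p = 0.00662, adjusted p = 0.270 with an estimated correlation), with manX (1.69) and manZ (1.71) highest. atpB lost its call without the 2 min (−0.60, adjusted p = 0.1), 6 min (−0.76, 0.0813) or 8 min library (−0.54, 0.218), under every other scaling (−0.62 to −0.84) and in limma-voom (−0.65) and DESeq2 (−0.62). It was at −1.21 without the 0 min library. sdhC lost it without the 0 min (−1.68, 0.0719) or 8 min library (−1.11, 0.113), with total counts or the stable RNAs (both −1.52) and in DESeq2 (−1.49). pgi lost it with the stable RNAs (−1.07, 0.0642). Without the 8 min library nuoA was at −0.33 and nuoB at 0.08, and without the 0 min library they were at 0.43 and −0.72 and cyoA passed (−0.88). atpI (−1.13), atpB (−0.79), sdhC (−1.44), pgi (−0.82), pfkB (1.57) and manX (1.59) did not pass with the file name number beside time.

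Genes for ribosomal proteins, RNA polymerase and nucleoid proteins stood higher as groups, with members on both sides. Of 33 genes for proteins of the large ribosomal subunit 20 rose and 1, rplY (−1.15), fell, with the same counts adjusted over the list alone (median 0.89; camera adjusted p = 3.47e-06, adjusted p = 0.250 with an estimated correlation), and rpmJ (2.24) and rplQ (2.51) were highest. rplU, at −0.52, did not pass (adjusted p = 0.084) but did without the 8 min library (−1.09, 0.00775). Of 21 genes for the small subunit 14 rose and 2 fell (15 and 2 adjusted over the list alone; median 1.15; camera adjusted p = 1.89e-05, adjusted p = 0.250 with an estimated correlation), with rpsU (−1.07) and rpsT (−0.81) lowest and rpsK (2.01) and rpsD (2.03) highest. For RNA polymerase and sigma factors 6 of 9 rose and 2 fell, also adjusted over the list alone (median 1.17; camera adjusted p = 0.00954, adjusted p = 0.450 with an estimated correlation): the core subunit genes rpoA (2.27) and rpoC (2.59) rose while rpoE (−2.39), the envelope stress sigma factor, and rpoH fell. Of 9 nucleoid proteins 6 rose and 1 fell, also adjusted over the list alone (median 1.11; camera adjusted p = 0.0334, adjusted p = 0.493 with an estimated correlation), with hupB (1.85) and lrp (1.53) against stpA (−3.33), while hns was at −0.15 (adjusted p = 0.610; −0.57 to 0.25 over the left-out libraries). The nucleoid list lost its call without the 8 min library (median less that of all genes 1.04 against 1.43 with it, camera adjusted p = 0.13). rplY (−0.90, 0.133) and stpA (−3.17, 0.143) lost their calls without the 0 min library. rpsU (−0.56), rpsT (−0.42), rplY (−0.37), rpoH (−1.64) and stpA (−3.79) lost theirs with the file name number beside time. There rplU was at 0.32 and hns at 0.13. rplY also lost it with the stable RNAs (−1.14, 0.0522) and stpA in DESeq2 (−3.28, 0.0795).

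RpoS genes, outer membrane proteins, fatty acid synthesis and the stable RNAs also stood above the average. Of 18 genes of the RpoS general stress response 12 rose and 2 fell (13 and 2 adjusted over the list alone; median 1.42; camera adjusted p = 6.87e-05, adjusted p = 0.280 with an estimated correlation), with the entericidin gene ecnB (2.05) and the transketolase gene tktB (2.03) highest and cbpA (−2.13) and otsB (−1.59) lowest. Of 13 major outer membrane proteins 9 rose and 1, tolC (−1.03), fell (10 and 1 adjusted over the list alone; median 1.11; camera adjusted p = 0.00149, adjusted p = 0.290 with an estimated correlation). In fatty acid synthesis 7 of 13 rose and 1, fabB (−2.84), fell, also adjusted over the list alone (median 0.92; camera adjusted p = 0.0289, adjusted p = 0.270 with an estimated correlation), with fabG (1.73) and fabZ (1.96) highest. All 4 stable RNAs rose, also adjusted over the list alone (median 2.30; camera adjusted p = 0.00113, adjusted p = 0.288 with an estimated correlation), and ffs, at 39 counts or fewer, had the smallest value (1.61, SE 0.67). ffs lost its call without the 2 min (1.21, adjusted p = 0.11) or the 8 min library (0.00022), with total counts (1.58) or the stable RNAs (1.56), in limma-voom (1.73) and in DESeq2 (1.77). It was at 3.44 without the 0 min library. Without the 8 min library ssrS was at 1.06 in place of 2.09 and ecnB at 1.32. tolC (−0.96), cbpA (−1.57), otsB (−1.36) and ffs (0.35) did not pass with the file name number beside time, nor did tolC with the stable RNAs (−1.12, 0.063).

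Genes for RNA decay and processing were the 1 list that stood lower. Of 17 genes 10 fell and 1 rose, with the same counts adjusted over the list alone (median log2 change −1.87, or −1.10 with the member at 0 counts at 8 min set to its floor; camera adjusted p = 0.0189, adjusted p = 0.250 with an estimated correlation). nudH, the RNA pyrophosphohydrolase gene (−3.98, SE 0.63), and rnt, which encodes RNase T (−3.79), were lowest, rne fell to a lesser extent, and pnp did not pass. The member that rose was yhbJ (1.38), now called rapZ, which acts in the processing of small RNAs. The list lost its call without the 8 min library (median less that of all genes −1.27 against −1.56 with it, camera adjusted p = 0.0688). rnt lost its call without the 0 min library, though its change was as large (−4.10, 0.081), and yhbJ without the 6 min library (0.97, 0.0645). nudH (−2.49), rnt (−2.80), rne (−1.72) and yhbJ (0.15) did not pass with the file name number beside time. Neither did rnt in DESeq2 (−3.77, 0.055) or yhbJ with the stable RNAs (1.31, 0.071).

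The other 16 lists did not pass, with camera adjusted p between 0.122 and 0.842. Among 23 aminoacyl-tRNA synthetase genes 9 fell and 2 rose (median −0.67), with argS (−2.77) and cysS (−2.41) lowest and pheT (1.68) and trpS (1.82) highest, and the list passed without the 0 min library (camera adjusted p = 0.00757), with the file name number beside time (0.00187), with no filter (0.036) and with a mean of at least 50 counts (0.0312). These calls use the preset correlation; over the 5 libraries the list had adjusted p = 0.604 with an estimated correlation. Of 10 acid resistance genes 3 rose and 4 fell (median −0.08): the regulators gadX (−4.06, SE 0.45) and gadW (−3.10) fell while the antiporter gene gadC (1.84) and hdeA rose. Of 8 small regulatory RNAs 5 rose and 2 fell (median 0.91), with gcvB (2.00) and sgrS (2.06) against csrB (−1.71) and csrC (−0.65), the pair that sequesters the regulator CsrA. csrB was abundant, with 23350 counts at 0 min and 1098 at 8 min. csrC lost its call without the 0 min (−0.52, 0.13) or 6 min library (−0.66, 0.0813), with DESeq2's size factors (−0.54, 0.0672) and with the stable RNAs (−0.74, 0.0673). csrC (−0.42), argS (−2.46), cysS (−3.10), pheT (1.35) and gadW (−1.76) did not pass with the file name number beside time. gcvB was then at 3.57.

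In the remaining 13 lists the higher and lower genes were 1 and 7 of 17 for iron uptake (median −0.40), 9 and 7 of 26 for cell division and peptidoglycan (0.06), 3 and 0 of 14 for heat shock (0.53), 4 and 3 of 14 for translation factors (0.51) and 0 and 4 of 13 for the SOS response (−0.92). For biosynthesis they were 1 and 6 of 13 for arginine and methionine (−0.82) and 4 and 7 of 21 for purines and pyrimidines (−0.05). For aromatic amino acids and histidine they were 5 and 4 of 24 (−0.38), and for branched-chain amino acids 5 and 2 of 11 (0.81). For cysteine and sulfate they were 1 and 2 of 5 (−0.12), where 1 of the 2 falls was the tRNA gene cysT (−7.79). They were 2 and 2 of 5 for cold shock (0.58), 0 and 3 of 4 for flagella (−1.97) and 0 and 1 of 8 for toxin-antitoxin modules (−0.27). Adjusted over the list alone the counts differed for cell division (11 and 8), translation factors (7 and 4), the SOS response (0 and 3), aromatic and histidine synthesis (4 and 3), branched-chain amino acids (6 and 4) and toxin-antitoxin modules (0 and 0). Where members at 0 counts at 8 min were set to their floors, the medians were −0.77 for arginine and methionine and −0.83 for the SOS response. Median and mean differed in sign for branched-chain amino acids (0.81 and −0.06) and cold shock (0.58 and −0.18), whose camera direction was up. For purines, cysteine, acid resistance and toxin-antitoxin modules the median lay above that of all genes (−0.32) while camera's direction was down. The direction of the cysteine list (mean −1.87) includes the tRNA gene cysT, and the list was not tested without it.

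**Figure D2:**
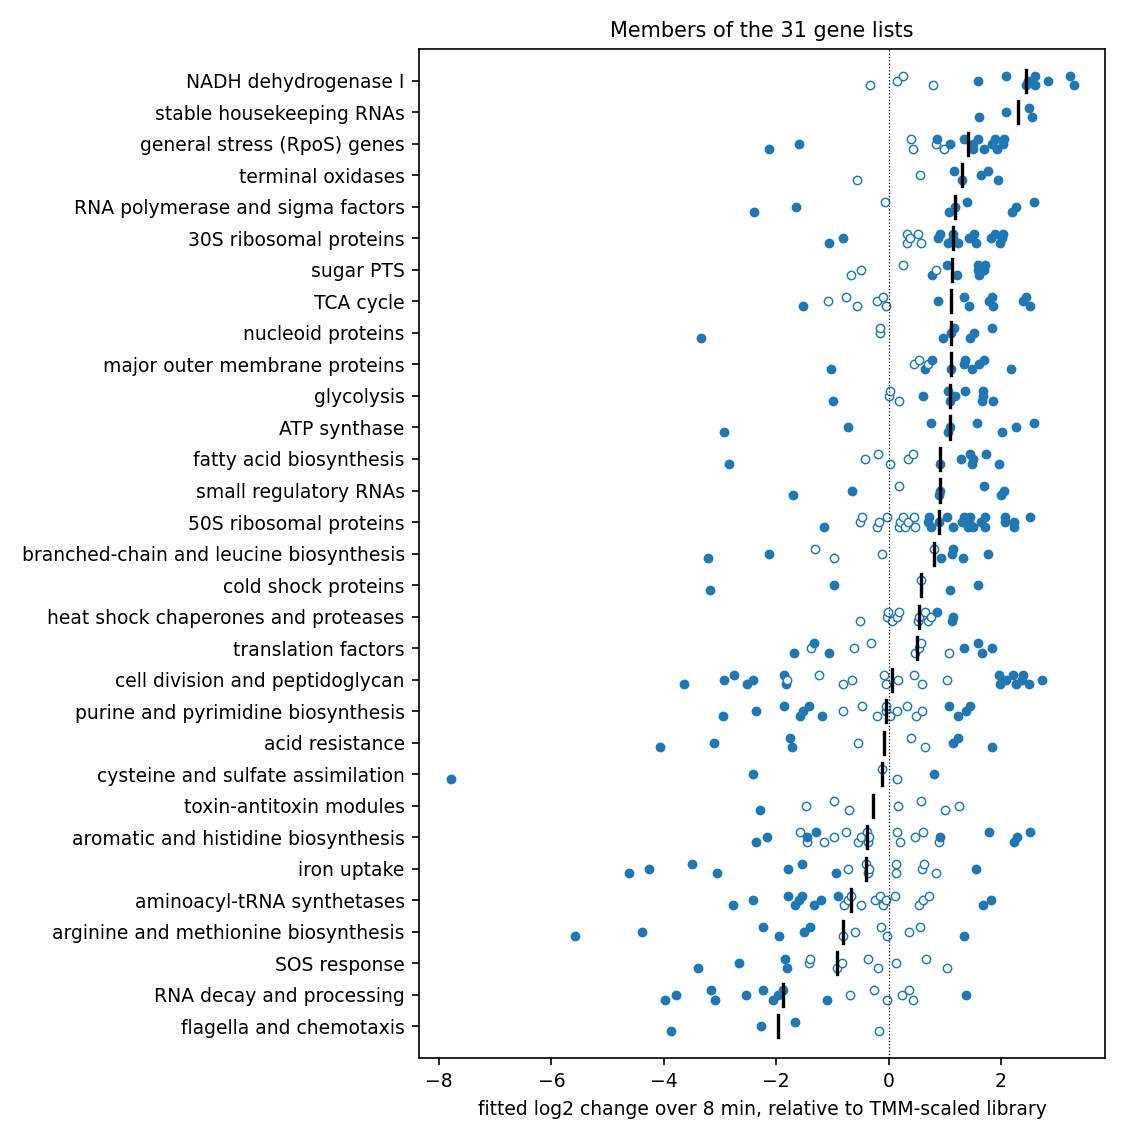
Fitted log2 change over 8 min on the TMM scale for each tested member of the 31 lists, ordered by list median (black bar); filled points passed edgeR's test over all genes and open points did not. NADH dehydrogenase I has the highest median (2.44), and RNA decay and processing (−1.87) and flagella (−1.97, 4 genes) the lowest.

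The next question was whether genes far from the promoter kept their level longer, since polymerases already on the DNA when rifampicin is added can still run on. Along operons the relative level increased from the promoter-proximal to the distal genes. In the 13-gene nuo operon the fitted log2 change was 0.15 at nuoA, −0.33 at nuoB, 1.58 at nuoF, 2.61 at nuoH and 3.29 at nuoN. In the atp operon it was −2.93 at atpI, 0.76 at atpE, 1.57 at atpA and 2.59 at atpC. In the rplJ to rpoC group it was 0.20 at rplJ, 0.70 at rplL, 2.20 at rpoB and 2.59 at rpoC, and in the sdh-suc group −1.53 at sdhC, −0.05 at sdhB, 1.83 at sucA and 2.52 at sucD. In the leu operon it was −2.13 at leuA and 1.31 at leuD.

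Over 20 operons with at least 3 tested genes (131 genes, gene order written before the data were examined), Spearman's rho of position against the 2 min over 0 min ratio averaged 0.353 and was above 0 in 17 (two-sided permutation of positions within operons, p = 0.00165, adjusted p = 0.00264 over 8 such tests). Against 4 min over 0 min the mean was 0.666 (17 of 20 above 0) and against the fitted slope 0.748 (18 of 20), each at p = 1e-05, the smallest that 100000 permutations can give. In the 11 operons with at least 5 tested genes the 2 min value was 0.297 (same permutation test, p = 0.0102). The exceptions to the slope pattern were the gal and ptsHIcrr operons, both at −0.5 with 3 genes each. Genes of an operon are not independent replicates, and the files' own 2 min library carries the mark GG against CC at 0 and 4 min.

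**Figure D3:**
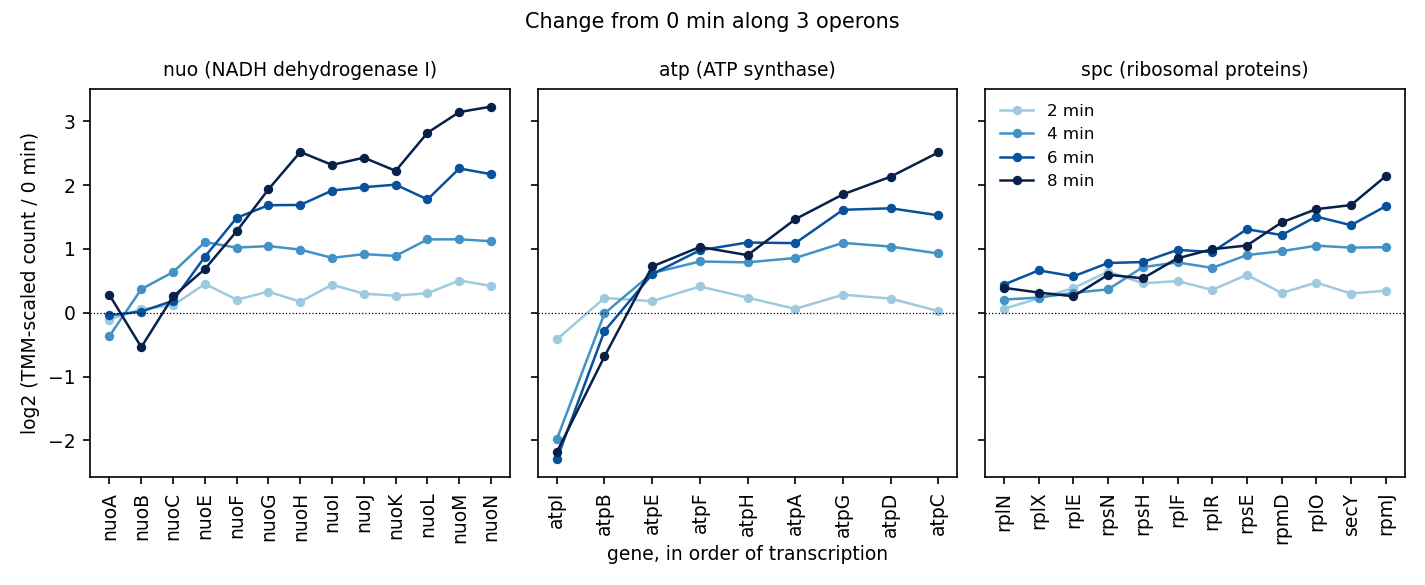
Log2 ratio of the TMM-scaled count to its 0 min value (vertical axis) for each gene of the nuo, atp and spc operons in order of transcription (horizontal axis), with 1 line per time from 2 min (light) to 8 min (dark). The 8 min line climbs from 0.28 at nuoA to 3.23 at nuoN and from −2.18 at atpI to 2.51 at atpC, while the 2 min line stays between −0.42 and 0.64.

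The series also carries 1 lifetime value per gene estimated by the authors, without a unit. A value stood in the authors' deposited table for 3587 genes, with a median of 7.15, quartiles of 5.13 and 11.5 and a range from 2.45 to 150, where 53 genes sat. Among tested genes, the authors' deposited table gave 150 to 25, among them ssrA, pepB (peptidase B), nuoH, atpC, phnI and phnF of the phosphonate cluster, wbbH and wbbI of the O-antigen cluster, ychN and ymbA. The shortest values in the authors' deposited table were those of dnaB, the replicative helicase gene (2.45), yebR (2.46), spr (2.47), exbB (2.52), nanR (2.72), yghW (2.74), yedJ (2.75), exbD (2.75), yliG (2.81) and ytfM (2.82), where exbB and exbD energise the uptake of iron complexes. On the trend those 10 fell, with fitted log2 changes between −3.82 (ytfM) and −5.76 (nanR), and the 10 named at 150 rose, from 2.44 (ychN) to 2.81 (wbbH). Those at 0 counts at 8 min were lower by at least 9.43-fold (dnaB), 8.66-fold (yebR), 4.89-fold (yghW), 3.86-fold (yliG), 3.25-fold (nanR and ytfM) and 3.19-fold (yedJ). ychN lost its call without the 8 min library (1.09, adjusted p = 0.268), and without the 0 min library exbD was at −6.46 and ytfM at −7.13. With the file name number beside time phnF (2.02), ymbA (1.45), yebR (−3.30), nanR (−1.88), yedJ (−4.31), exbD (−2.35), yliG (−3.98) and ytfM (−1.94) did not pass and ychN was at 4.48. nanR ran from −20.84 to −4.74 over the left-out libraries and did not pass in DESeq2, where it was at −7.18.

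Lifetime value and trend followed the same order. Over 2206 genes the Spearman correlation between the authors' deposited table and the fitted slope was 0.984 and Pearson's r was 0.516, rising in size to −0.963 with the inverse of the lifetime (each permutation p = 1e-05, the smallest possible, adjusted p = 1.4e-05 over 7 correlations). These are correlations across genes, which are not independent replicates, and both sides come from the same 5 libraries. The next relation used the 581 genes with a mean of at least 100 counts and a value below the ceiling of 150. In them the inverse of the value in the authors' deposited table lay on a straight line against the slope of log counts (r = −0.9996). The constant was 1.59, where a lifetime to 1/e in minutes would give 1 and a halving time 0.693. Genes at the ceiling or without a value were left out. Its zero point was at a slope of −0.042 per min, beside −0.044 for the stable RNAs and −0.144 for the library totals. The scale of the lifetime value is therefore not minutes on either of these definitions, and the values are used here only to order genes. The 33 tested genes without a lifetime value had log2 changes of 2.44 or more, and 30 of them, nuoM, nuoN and yfbP included, lay above ssrA, as did 12 genes with a value, yfgJ and wbbH among them.

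**Figure D4:**
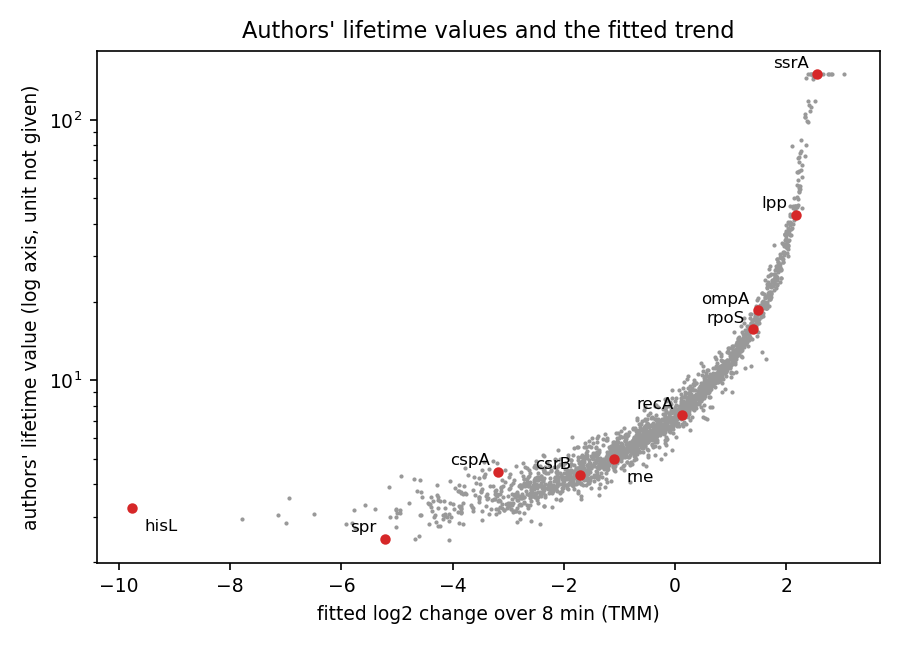
Lifetime value from the authors' deposited table (log axis, unit not given) against the fitted log2 change over 8 min on the TMM scale, 1 point per gene for 2206 genes, 10 named genes in red. The points form 1 rising curve that steepens towards ssrA at 150, with spr at 2.47 and a log2 change of −5.21 near the lower end.

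Whether abundant transcripts are those that last was asked next, and no single direction was found. Over all 3587 genes of the authors' deposited table the Spearman correlation of lifetime with the level at 0 min was −0.180 (permutation p = 1e-05, the smallest possible), and Pearson's r with log2(CPM + 1) was −0.039 (p = 0.0201, adjusted p = 0.0235). With the mean level over the 5 libraries in its place, the Spearman correlation over the 3587 genes was −0.013 (permutation p = 0.429). Among the 2206 tested genes, which leave out those with few reads, the correlation with the level at 0 min was 0.164 (p = 1e-05). Tested genes were also put in 4 equal groups by level at 0 min. From the lowest to the highest, the groups' median lifetime value in the authors' deposited table was 6.43, 5.61, 6.08 and 9.48. The filter used the mean count over the 5 libraries, so genes with few counts at 0 min entered only if later counts stayed high. This can favour lasting genes in the lowest group. Lifetime values followed the slope of the same counts, so error in the 0 min count enters both sides of correlations with that level. The signs therefore cannot decide whether abundant transcripts last longer. lpp, with 13529 counts at 0 min, had a value of 43.3 in the authors' deposited table, while csrB, with 23350, had 4.33.

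The lists were also placed by lifetime. By the authors' deposited table, 6 lists had median lifetime values above the 97.5th percentile of 10000 random lists of the same size matched on level at 0 min. Another 2 lay below the 2.5th percentile. With independent members 1.55 of 31 lists would lie outside. The random lists draw genes singly, while members of real lists often share an operon, so 1.55 is not the number expected here. High medians in the authors' deposited table belonged to the stable RNAs (96.3), NADH dehydrogenase I (27.9), small regulatory RNAs (17.1), the RpoS genes (17.0), the sugar phosphotransferase system (13.4) and branched-chain amino acid synthesis (10.6). Low medians in the authors' deposited table belonged to the aminoacyl-tRNA synthetases (5.70, against 8.48 for matched lists) and RNA decay and processing (4.82, against 7.18). The ribosomal proteins of the large subunit (10.8, 14.4th percentile) and small subunit (13.1, 58.1th) in the authors' deposited table were inside the range of lists as abundant as they are. So were ATP synthase (49.95th), the TCA cycle (76.8th), glycolysis (87.3th) and the terminal oxidases (93.8th). The same held for RNA polymerase (87.8th), nucleoid proteins (91.1th), outer membrane proteins (75.9th) and fatty acid synthesis (80.4th). All these lists stood higher in the trend, where level was not matched. Percentiles describe these libraries and are no p-values.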

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

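Of the tests in this part, the ratio of rnpB to ssrA was chosen only after the result was seen, and the term for the mark in the file names was added after seeing the data. Reads that fell in no gene are counted in the authors' files but belong to no comparison of the report, which is why they are given here: their share was 7.67% of all reads at 0 min (95% exact binomial interval 7.61% to 7.73%) and 5.02% at 8 min (4.94% to 5.10%). It was 7.08%, 6.13% and 5.90% at 2, 4 and 6 min. The intervals cover counting error only, and where in the genome these reads lie is not known from the tables.

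The libraries at 2 and 6 min share the mark GG in their file names and differed from the other 3 in a few abundant RNAs. rnpB over ssrA was 0.319, 0.234, 0.34, 0.242 and 0.3 at 0, 2, 4, 6 and 8 min, and the higher of the GG values was 0.807 times the lowest of the others, for RNAs without near-identical copies, so reads shared between copies would not account for that ratio, nor would the number in the file names, since 2 min over 0 min, which share it, was 0.734. With a term for the GG libraries beside time, 5 genes passed (rrsG, rrsE, rrsC, rrlC and ssrS, all lower in GG), while of the other 9 pairs of libraries 7 called 1 gene or none, 2 and 4 min called 12 and 0 and 8 min called 58. For the 4 ribosomal genes a shift of reads between near-identical copies stays open, since other copies went the opposite way: rrlD held 19% and 18.9% of 23S reads at 2 and 6 min against 6.68%, 8.16% and 13.7% at 0, 4 and 8 min, and rrsH 63.8% and 75.4% of 16S reads against 41.9%, 54.3% and 68.3%. A difference in library preparation may lie behind the pattern and stays open, since 2 of the other pairs called more, and no biological explanation was tested.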

How the results depend on the processing

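The alternatives were fixed before the data were examined, except the mark term, the stable RNA scale for single steps, single stable RNAs as scale, the 8 over 4 min step along operons and lifetimes below the ceiling, which were chosen after seeing the data. Of the comparisons of named genes with an alternative, 1522 kept direction and side of the threshold, 88 lost the call, 12 gained one and 13 turned; for lists these were 316, 33, 5 and 14. Summary values stayed in 59 comparisons, moved in 19, lost the call in 1 and turned in 1. Spearman's rho of lifetime and trend stayed between 0.818 and 0.997, and that of operon position, 0.353 at 2 over 0 min, was 0.297 in operons of at least 5 tested genes, 0.666 at 4 over 0 min, 0.748 for the slope and 0.596 at 8 over 4 min. The cause was not tested where nothing else is said. The genes that turned had not passed in the report, cspA apart. A list turned where camera's direction did; its values here are medians less that of all genes, which can keep their sign. No paired analysis was possible because each time has 1 library. Depth limits genes under 10.2 CPM at 8 min.

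With total counts 84 genes rose and 1306 fell (515 and 616 with TMM), 7 lists passed, the 8 min median was −1.62, and gpmI (−0.052), the aromatic and histidine list (−0.084) and toxin-antitoxin modules (0.069) turned. With the stable RNAs 1925 genes passed (1131 with TMM), 1 rose and 1924 fell, and the 8 min median was −2.80. On that scale 3 lists passed, among them the stable RNAs that set it. There gpmI (−0.065), translation factors (0.73), cold shock (0.84), aromatic and histidine synthesis (−0.058) and toxin-antitoxin modules (0.095) turned. These scalings by construction move all genes together. With no filter gpmI (−0.10) and flagella (0.21) turned, the latter with more genes tested. With a mean of at least 50 counts, and so fewer genes, 608 passed, 281 higher and 327 lower, 5 lists passed, branched-chain synthesis (0.37) turned, and the median lifetime value in the authors' deposited table was 8.71. With the file name number beside time 250 passed, 187 higher and 63 lower, and recA (−0.44), rplU (0.32), hns (0.13), acid resistance (0.39) and branched-chain synthesis (0.58) turned; that number splits early from late times. In DESeq2's Wald test 398 genes fell. The correlation of lifetime with level was −0.180 in the authors' deposited table, −0.013 with the mean level (p = 0.429, permutation) and 0.164 among tested genes. Against random lists not matched on level 14 lists lay outside, and 8 against matched ones.

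Over the left-out libraries 913 to 1161 genes passed, 453 to 520 higher and 451 to 641 lower, and 13 to 16 lists passed. Values ran from −5.97 to 0.28 for cspA, −0.57 to 0.25 for hns, −0.15 to 0.070 for gpmI, −0.23 to 0.74 for rpsO, −0.72 to 0.075 for nuoB and −0.33 to 0.43 for nuoA. For lists they ran from −0.024 to 0.35 for acid resistance, −0.084 to 1.24 for cold shock, −0.18 to 0.29 for aromatic and histidine synthesis and −0.64 to 0.57 for toxin-antitoxin modules.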

Other observations

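The lists of regulators, tRNA genes and leader peptides in this part, and their tests, were chosen only after the steepest falls were seen, and the 8 over 4 min operon test was added after seeing the data, while the time-order and other operon tests were written before. Genes of transcription regulators stood lower than other genes. Of 50 tested, 31 fell and 2 rose, and with nanR, dgsA, exuR, mntR, gcvA and pdhR, which were seen among the steepest falls before the list was written, left out, 25 of 44 fell and 2 rose (median log2 change −1.71, or −1.45 with members at 0 counts at 8 min set to their floors; camera of limma, p = 0.000356, and p = 0.185 with an estimated correlation). The falls included fnr (−3.85, SE 0.51), the regulator of anaerobic growth, malT (−4.07, SE 0.54), the activator of maltose genes, crp (−1.96), the cAMP receptor protein, and fur (−1.54), the iron repressor. The 2 that rose were zntR (2.54), which responds to zinc, and glnG (2.47), the nitrogen regulator at the end of its operon. ompR (−0.08, adjusted p = 0.875) and oxyR (0.30, 0.523) did not pass.

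Most tested tRNA genes fell. The 86 tRNA genes of the files held 3168 reads at 0 min and 163 at 8 min, and 14 had none at any time. Of 25 tested 20 fell and 0 rose, and with cysT, leuZ, leuT, hisR and tyrU, seen among the steepest falls, left out 15 of 20 fell (median −2.81, or −1.74 with floors; camera of limma, p = 0.00123, and p = 0.331 with an estimated correlation), among them leuW (−3.86, SE 0.51), lysT (−3.23) and serV (−1.22, SE 0.34). Many have near-identical copies and are uncertain. Mature tRNAs are long-lived, so these reads may come mostly from precursors or from RNA that passes the size limits of the library preparation, and the median of −2.81 cannot separate these.

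Of 9 tested leader peptide genes 7 fell, and tnaC (0.14), ahead of tnaA, and pyrL (0.84), ahead of pyrB, did not pass. In 8 pairs the leader's log2 change was below that of the operon's first structural gene, by −0.54 for pyrL to −8.99 for hisL, whose fitted value is no bound, with thrL at −4.58 and thrA at 0.18. The leaders of 5 of these pairs had been seen among the steepest falls, so a p over all 8 would rest on genes chosen for the pattern and is not given. In the 3 pairs not seen before, pheL, tnaC and pyrL, the mean difference was −1.44 (SD 0.92, exact sign-flip p = 0.25, the smallest 3 can give), too few to decide whether leader RNAs decay faster. Position at the 5′ end alone could give such a gap too: in the 4 operons with a tested second gene, all but pyrL seen before, the leader's step less the next step was −3.23 (exact p = 0.125, the smallest 4 can give), which leaves it open.

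For the operon gradient, polymerases that had started before rifampicin and ran on to the operon's end would raise distal genes early, and the mean rho at 2 min over 0 min was 0.353 (permutation p = 0.00165, 20 operons). Slower decay of distal genes throughout would leave a gradient between 8 and 4 min, and in operons of at most 5 listed genes it was 0.5 (permutation p = 0.00364, 12 operons). Operon lengths were not measured and the 12 include rpoB and rpoC, so run-on past 4 min may be part of that value and the test does not isolate slower decay. The mark GG of the 2 min library against CC at 0 min would not give a gradient at 4 min, also CC, where it was 0.666. The 4 over 0 min ratio does cross the file name number, 7 at 0 min and 8 at 4 min. It also sets 265650 reads in genes against 737107. The 2 over 0 min ratio shares the number but not the mark. No biological comparison beyond these was possible in 1 strain and treatment.

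The 5 libraries can be put in 60 orders up to reversal, and the real order called 1131 genes, more than any other: 1 of 60 reached that number, and the next, with 6 and 8 min exchanged, called 857. Slopes of neighbouring genes in the file order were related (Spearman's rho 0.464 over 1654 pairs, permutation p = 1e-05, the smallest possible), with a median gap of 0.94 against 1.56 for random pairs. Against the stable RNAs, nuoN was at 1.61 times its 0 min level (1.33 to 1.94) at 8 min and yfbP at 3.22 times (1.58 to 7.09), a pair picked after the values were seen from the 12 of 2239 genes whose 95% counting interval lay above 1 at that time.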
